A study of Mus musculus with 18 samples.

How the data were processed

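The series holds RNA sequencing libraries of natural killer (NK) cells from mouse spleen, cultured for 7 days at 1% oxygen with 1700 U/ml of interleukin 2 (IL-2). Per the labels, 3 mouse lines carried loxP-flanked (flox) alleles of Hif1a, of Ahr or of both genes, and in each line cells with Ncr1-iCre (here called KO, for knockout) stand beside cells of the flox genotype without it. This makes 6 groups of 3 biological replicates, 18 libraries in all. The labels name a strand-specific mRNA library protocol for DNBSEQ sequencing.

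The authors' processing, per the labels, used Trim Galore 0.6.4, kallisto 0.4.6 and edgeR 3.17 with the GRCm39 build; settings and transcript annotation are not stated. The deposited count values are expected counts per gene as kallisto estimates them, in estimated counts that are not normalised, with 65.5% to 67.8% of the values above 0 not whole numbers. The deposited CPM values are log2 CPM on the log2 scale; they were recomputed from the counts with a prior count of 2 and differed by at most 7.1e-15. Tests used the estimated counts. They were rounded to whole numbers for DESeq2 only.

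The table has 56953 gene identifiers, of which 52029 matched a symbol in the gene name table. The 4924 without a symbol hold 0.32% of all counts and were tested but not named. Chromosomes and gene order came from a GENCODE annotation of the previous mouse build and are used as numbers and neighbour order only, since the counts were made on GRCm39. Members of the gene lists listed under newer symbols were matched by identifier, which found 518 of 518 list genes.

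Library totals lay between 54420649 and 55732940 counts, with 24103 to 25669 genes above 0. Between replicates of a group, counts varied 16.3 to 68.1 times more than counting error alone would give (chi-square per degree of freedom). Over genes as a whole, replicate spread more than depth therefore set the precision. This measure is weighted toward genes with high counts and does not speak for genes with few counts. CPM values in the text are scaled with TMM factors and given as mean and standard deviation (SD) of 3 libraries. Errors beside log2 fold changes are standard errors (SE), taken as the fold change divided by the square root of its F statistic.

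Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by group (16747 genes tested), 1 mean per group over all 18 libraries, robust quasi-likelihood fits (common biological coefficient of variation 0.117, 12 residual degrees of freedom) and quasi-likelihood F tests, 2-sided. A gene was called, and is described as having risen or fallen, at a Benjamini-Hochberg (BH) adjusted p under 0.05, adjusted within each comparison over all genes tested. The 3 main comparisons set each KO group against the flox group of its own line. Further contrasts tested the differences between these 3 effects, the departure of the Hif1a Ahr KO effect from the sum of the single KO effects (on the log2 scale), and, with an F test, differences between the 3 flox groups. Overlaps of called genes were compared with the number expected if the calls were independent.

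Gene lists were fixed before the data were examined, 20 for pathways and 14 for other cell types and checks. A total of 32 lists had at least 3 tested genes; the mast cell and basophil list had 2 and the erythroid list 0. Lists were tested against all other genes with limma 3.58.1 camera at its preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run as alternatives. Member counts are given at the p adjusted over all genes and, where so stated, adjusted over the list alone; where no separate count is given the counts were the same.

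Genes were named by a rule written before the data were examined. It takes Hif1a, Ahr and Ncr1; in each main comparison the 6 largest rises and the 6 largest falls among called genes with a mean of at least 1 CPM over the 6 libraries, no overlap between the 3 KO and the 3 flox values and an informative symbol; up to 4 called members of each list, by adjusted p; the 4 genes with the smallest adjusted p in each direction for each difference of effects, and 8 genes for the flox groups. Members of the lists that were not called may be named with their values. Some genes that the rule takes are not reported here. Genes of the chromosome 9 run and the neighbours of Ncr1 were chosen after their values were seen.

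Whether replicate numbers mark shared preparations was checked before calls were compared, from the correlation of the libraries' deviations from their group means over genes with a mean of at least 5 CPM. The rule took numbers as pairs where the correlation of every same-numbered KO and flox pair was above 0.1. It held for the Hif1a line (0.3 to 0.53) and the Ahr line (0.33 to 0.53) and failed for the Hif1a Ahr line (0.07 to 0.45). Same-numbered flox libraries of the Hif1a line correlated negatively with those of the other two lines (-0.62 to -0.25 and -0.44 to -0.3). Those of the Hif1a Ahr and Ahr lines correlated at 0.19 to 0.42 (at most 0.08 between other numbers), which meets the same rule, so these flox libraries may not be independent between the 2 lines. The labels do not state what the numbers mark.

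The alternatives were RLE size factors, upper quartile scaling, DESeq2 1.42.0, limma voom, no filter on low counts, a mean of at least 5 CPM, a fit of the compared groups only, a replicate block, leaving out each replicate, and an absolute log2 fold change of at least 1. Chosen after the data were seen were a covariate for the ratio of Y-linked to Xist counts, leaving out genes linked to the Cre locus (here the chromosome 9 run, Ncr1 and its neighbours, whose place relative to Cre was not tested), and leaving out the 2 libraries highest in T cell genes. No scaling moved the median of all genes beyond -0.03 to 0.017 (log2) in any comparison. On counts simulated with each gene's mean over all libraries and its spread within groups, with 200 genes changed, the main comparisons recovered 38.8% to 56.7% of genes changed 1.5-fold, 59.7% to 71.6% at 2-fold and 83.3% to 90.9% at 4-fold. The test of departure from additivity recovered 7.5%, 44.8% and 65.2%. In a simulation with 1 list doubled, that list and no other was called. Its genes were drawn independently of each other, so it does not check list calls where genes are correlated. Figures were drawn with Matplotlib 3.10.9 under Python 3.11.15. Transcript-level changes, splicing and the deleted exons cannot be read from gene-level counts and were not analysed here.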

Results

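RNA was sequenced from NK cells, lymphocytes that kill infected or transformed cells. The cells came from mouse spleen and were grown with IL-2 at 1% oxygen for 7 days. The 18 libraries form 6 groups of 3: Hif1a flox and Hif1a KO, Ahr flox and Ahr KO, and Hif1a Ahr flox and Hif1a Ahr KO. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1. Ahr encodes the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor that shares its partner Arnt with HIF-1. Total counts per library ran from 54420649 to 55732940. On the first principal component, which held 51.1% of the variance of the 1000 most variable genes, Hif1a KO cells stood at 42.2 ± 3.7 and Hif1a Ahr KO cells at 37.8 ± 4.2 (SD, n = 3). The means of the other 4 groups lay between -24.1 and -15.3.

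The targeted genes come first. Gene-level Hif1a transcripts did not fall where Hif1a was deleted. They rose from 60.3 ± 4.28 to 180 ± 32.0 CPM (SD, n = 3) in Hif1a KO cells (log2 change 1.58 ± 0.11, SE; adjusted p = 6.61e-09). In Hif1a Ahr KO cells they rose from 59.8 ± 2.26 to 192 ± 25.5 CPM (1.68 ± 0.11; adjusted p = 3.07e-09). In Ahr KO cells Hif1a stood at 67.2 ± 1.9 CPM beside 62.5 ± 3.79 in Ahr flox cells (adjusted p = 0.663). Ahr transcripts were not called in any of the 3 comparisons. They stood at 76.5 ± 2.35 CPM in Ahr flox and 92.1 ± 4.4 in Ahr KO cells (adjusted p = 0.515). They stood at 66.3 ± 13.1 in Hif1a Ahr flox and 55.5 ± 13.5 in Hif1a Ahr KO cells (adjusted p = 0.374), and at 31.6 ± 6.7 in Hif1a flox and 44.7 ± 10.5 in Hif1a KO cells (adjusted p = 0.0731). The last became a called rise without Hif1a flox replicate 2 (0.0251) or Hif1a KO replicate 3 (0.0327). With same-numbered replicates as pairs, Ahr was called higher in Hif1a KO (adjusted p = 2.34e-04) and Ahr KO cells (adjusted p = 0.0337). The same fit called it lower in Hif1a Ahr KO cells (-0.27; adjusted p = 0.0162), a line whose replicate numbers failed the pairing rule. A count summed over a whole gene includes transcripts that lack the deleted exon, so these counts check neither deletion. Ncr1, which encodes the NK receptor NKp46 and which gives Cre its driver by the name of the Cre line, rose in all 3 KO groups. Its log2 change was 0.92 ± 0.10, 0.97 ± 0.10 and 1.06 ± 0.10 in the Hif1a, Ahr and Hif1a Ahr lines.

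**Figure D1:**
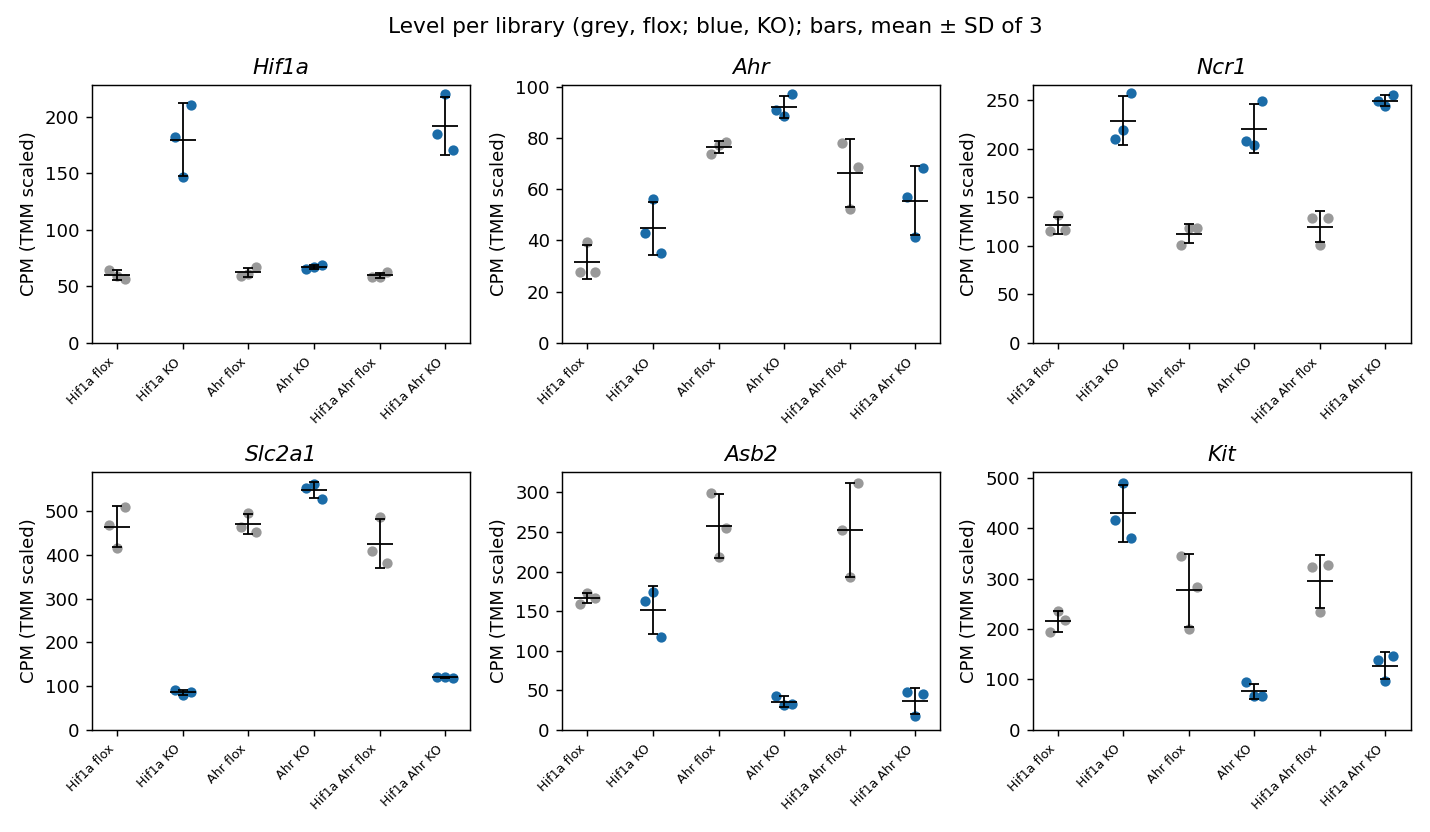
Level of 6 genes per library in CPM (y axis, linear, from 0) in the 6 groups (x axis); grey points are flox and blue points KO libraries, and bars give the mean and SD of 3. Hif1a rose to a mean of 180 CPM in Hif1a KO and 192 CPM in Hif1a Ahr KO cells, Slc2a1 fell to 85.3 and 120.0 CPM there, Asb2 fell to 35.7 CPM in Ahr KO and 36.6 CPM in Hif1a Ahr KO cells, and Kit fell to 76.2 CPM in Ahr KO cells.

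The Hif1a KO comparison asks which transcripts change where Hif1a is deleted in NK cells held in low oxygen. In every line the KO cells carry Cre and the flox cells do not, and no group has Cre alone. An effect of Cre therefore cannot be told apart from one of the deletion within a line. Glycolysis genes fell together, in 18 of 19 tested members (19 adjusted over the list alone). The exception was Pfkm at -0.15 (adjusted p = 0.085). The aldolase Aldoa fell from 3605 ± 270 to 678 ± 32.9 CPM (SD, n = 3), and the glucose transporter Slc2a1 from 465 ± 47.2 to 85.3 ± 6.22 CPM. The phosphofructokinase Pfkl fell by 3.10 ± 0.11 (log2, SE) and the enolase Eno1 by 2.50 ± 0.10. Of 28 HIF targets outside glycolysis 26 fell. Among them were P4ha1, a collagen prolyl hydroxylase (by 3.07 ± 0.14), Narf (by 2.50 ± 0.11), the fructose 2,6-bisphosphate regulator Pfkfb3 (by 2.11 ± 0.10) and the oxygen sensor Egln1 (by 1.38 ± 0.08). Rora rose by 0.88 ± 0.26 and Pfkfb4 stood at -0.34 (adjusted p = 0.13). Both lists were called by camera with a median of -2.19 each (adjusted p = 2.97e-26 for glycolysis and 3.52e-23 for the other HIF targets). Both calls held with an estimated correlation (adjusted p = 0.0338 and 0.0194). Car12, Anxa2 and Rora belong to a run of neighbouring chromosome 9 genes described further on. Of the 25 HIF targets outside that run 24 fell.

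In total 5923 of 16747 genes were called in Hif1a KO cells, 2948 higher and 2975 lower. At least 2-fold changes numbered 520 and 1095. The largest falls were in the fatty acid desaturase Scd1 (-5.44 ± 0.93), the mucin Muc2 (-5.25 ± 0.50), Smtnl2 (-5.07 ± 0.25), the adenylate kinase Ak4 (-4.86 ± 0.24), the mitochondrial protein gene Mgarp (-4.81 ± 0.28) and the transcription factor Foxn1 (-4.78 ± 0.41). The largest rises were in the p38 kinases Mapk12 (4.21 ± 0.46) and Mapk11 (3.54 ± 0.32), the nicotinamide nucleotide transhydrogenase Nnt (3.87 ± 0.99), and the inhibitory receptor Cd300a (3.51 ± 0.25). The glucuronosyltransferases Ugt1a9 (3.73 ± 0.47) and Ugt1a6a (3.49 ± 0.46) also rose, but shared exons leave the split of counts among the Ugt1a genes uncertain.

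Cholesterol synthesis also fell, in 22 of 23 tested members with a median of -1.14. The sterol regulator Insig1 fell by 1.14 ± 0.09, lanosterol synthase Lss by 1.30 ± 0.13 and Stard4 by 0.98 ± 0.10. Camera called the list (adjusted p = 7.81e-13; adjusted p = 0.504 with an estimated correlation). Cell cycle genes rose in 27 of 36 members (28 adjusted over the list alone) and none fell, with a median of 0.45. Kif11 rose by 0.86 ± 0.11, Top2a by 0.73 ± 0.11 and Ccna2 by 0.62 ± 0.09. For this list adjusted p was 3.38e-09 (adjusted p = 0.504 with an estimated correlation). All 13 mitochondrially encoded transcripts rose, with a median of 0.73, including mt-Co1 (0.68 ± 0.12) and mt-Atp6 (0.84 ± 0.16). The list had adjusted p = 2.37e-05, and adjusted p = 0.504 with an estimated correlation. Their share of all counts was 3.33 ± 0.15% in Hif1a KO and 1.96 ± 0.27% in Hif1a flox cells (SD, n = 3). Nuclear-encoded oxidative phosphorylation genes moved less, with 8 of 42 called higher, 1 lower and a median of 0.11 (3 and 0 adjusted over the list alone). They were led by Ndufa4 (0.95 ± 0.12) and Sdhb (0.51 ± 0.09). That list was called at adjusted p = 0.021 (0.0624 without Hif1a flox replicate 2; adjusted p = 0.735 with an estimated correlation). TCA cycle genes had 8 of 17 members higher, with citrate synthase Cs at 0.33 ± 0.06 and Suclg1 at 0.44 ± 0.09. The list's adjusted p was 0.0451, with 0.0563 without Hif1a flox replicate 2, 0.086 without Hif1a KO replicate 3, 0.0524 with same-numbered replicates as pairs, and adjusted p = 0.555 with an estimated correlation. Of 20 genes of the ATF4 and amino acid response, 8 rose, such as Sesn2 (0.67 ± 0.10) and Mthfd2 (0.81 ± 0.14), and 1 fell, Ddit3 at -0.52. This list had adjusted p = 0.0451 (adjusted p = 0.735 with an estimated correlation). The call was lost without Hif1a flox replicate 1 (0.0571), Hif1a flox replicate 2 (0.202) or Hif1a KO replicate 3 (0.22).

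Among genes of NK cell function, the pore-forming protein gene Prf1 fell from 3576 ± 718 to 716 ± 266 CPM (SD, n = 3), and the granzymes Gzmd and Gzmg fell by 2.27 ± 0.34 and 3.37 ± 0.54. Granzyme paralogs share sequence, so the split of counts among them is uncertain. Of 16 cytotoxic effector genes 9 fell (10 adjusted over the list alone) and 3 rose, such as Lamp1 (0.57 ± 0.06). The list was called at adjusted p = 0.0451 (0.0605 and 0.0661 without Hif1a flox replicate 1 or 3; adjusted p = 0.504 with an estimated correlation). NK receptors had 11 of 25 members higher, such as Klrb1f (1.64 ± 0.18) and Cd96 (0.58 ± 0.10), and 4 lower, such as Cd244a (-0.48 ± 0.07). The receptor list had adjusted p = 0.0354 (0.0531 without Hif1a flox replicate 2; adjusted p = 0.504 with an estimated correlation). Interferon response genes were higher in 12 of 28 members (1 lower adjusted over the list alone), among them Ifit2 (1.11 ± 0.14), Usp18 (1.44 ± 0.22) and Gbp3 (0.75 ± 0.07). The interferon list had adjusted p = 0.00411, and adjusted p = 0.512 with an estimated correlation. Checkpoint and costimulatory receptors were not called as a list (adjusted p = 0.0917), with 6 of 14 lower and 2 higher. Lower were Havcr2, which encodes TIM-3 (-1.79 ± 0.24), Entpd1, which encodes CD39 (-1.47 ± 0.19), and Tnfrsf9 (-1.28 ± 0.11). Circulating mature NK genes went both ways, 4 higher and 7 lower of 16 (6 higher adjusted over the list alone; list adjusted p = 0.87). The transcription factor Zeb2 rose by 0.84 ± 0.10, while Prdm1 fell by 1.28 ± 0.19.

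The remaining pathway lists were not called in Hif1a KO cells. ILC1 and tissue residency genes had 3 of 15 higher and 4 lower, with a median of 0.48 but a mean of -0.12 and a downward test (adjusted p = 0.663). The integrin Itga1 fell by 1.88 ± 0.19 and Kit rose by 0.99 ± 0.21. The AhR battery had 3 of 13 higher (4 adjusted over the list alone) and 2 lower (adjusted p = 0.312), with the quinone reductase Nqo1 up by 2.83 ± 0.24 and Selenbp1 down (-1.40 ± 0.18). HIF and AhR partners had 1 of 11 higher, Arnt (0.44 ± 0.07), and 4 lower. Among the lower were Arnt2 (-3.00 ± 0.31) and Epas1, which encodes HIF-2 alpha (-2.25 ± 0.49; list adjusted p = 0.334). Cytokines and chemokines had 6 of 14 higher, such as Tnf (2.09 ± 0.37), and 1 lower, Flt3l (-0.81 ± 0.17; list adjusted p = 0.222). The IL-2 and STAT5 response had 2 of 15 higher and 4 lower (3 and 4 adjusted over the list alone; adjusted p = 0.651), with the kinase Jak3 at -1.43 ± 0.09. NRF2 antioxidant genes had 5 of 13 higher, such as Gclm (1.21 ± 0.11), and 2 lower, such as Pgd (-0.76 ± 0.06). Adjusted over the list alone these were 6 and 3 (list adjusted p = 0.222). Autophagy genes had 4 of 15 higher, led by Atg7 (0.46 ± 0.08; list adjusted p = 0.214). Ribosome biogenesis genes had 1 of 18 higher and 5 lower, led by Mybbp1a (-0.46 ± 0.08; list adjusted p = 0.0917, 0.03 without Hif1a flox replicate 3).

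Markers of other cell types moved as follows in Hif1a KO cells. The T cell list had 4 of 12 members lower, Cd3g (-3.12 ± 0.33), Cd3d (-2.24 ± 0.25), Trac (-0.40 ± 0.12) and Trbc2 (-0.36 ± 0.07), while Cd3e stood at -0.27 (adjusted p = 0.83). The T cell list had adjusted p = 0.0917 (0.0216 without Hif1a flox replicate 1 and 0.0301 without Hif1a KO replicate 2). Neutrophil markers were called lower in 4 of 5 members (5 adjusted over the list alone; list adjusted p = 0.0122; adjusted p = 0.504 with an estimated correlation) at low levels. S100a9 stood at 1.42 ± 1.37 CPM in Hif1a flox and 0.0228 ± 0.026 in Hif1a KO cells. Elane stood at 0.120 ± 0.129 CPM in Hif1a flox and at 0 in all 3 Hif1a KO libraries. Dendritic cell markers had 2 of 6 lower and 1 higher (3 lower adjusted over the list alone; adjusted p = 0.575). The class II gene H2-Ab1 fell by 2.94 ± 0.16 while Cd74 rose by 1.37 ± 0.27. Macrophage and monocyte markers had 3 of 5 lower, such as Csf1r (-3.24 ± 0.72), and Cd68 higher (0.75 ± 0.20; list adjusted p = 0.226). B cell markers had adjusted p = 0.372 (1 of 3 higher), plasma cell markers 0.334 (1 of 3 lower), and platelet and megakaryocyte markers 0.748 (0 of 3 called). The remaining lists of this kind had adjusted p of 0.594 (ILC2 and ILC3, 1 of 4 higher, 0 adjusted over the list alone), 0.222 (stroma and endothelium, 2 of 3 lower) and 0.895 (sex-linked genes, 0 of 5 called). Immediate early and heat shock genes had 4 of 10 lower, such as Hspa1b (-1.26 ± 0.21), and 1 higher adjusted over the list alone. They had a median of -0.21, a mean of 0.03 and a downward test (adjusted p = 0.378). The mast cell and basophil list had 2 tested members, both lower: the protease Mcpt8 (-2.70 ± 0.41) and Cpa3 (-0.97 ± 0.36). The Cpa3 call was lost without Hif1a flox replicate 1 (0.0877) or 3 (0.173), and without Hif1a KO replicate 1 (0.0812), 2 (0.138) or 3 (0.0713). No erythroid marker passed the filter on counts.

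The Ahr KO comparison asks which transcripts change where Ahr is deleted in the same conditions, again with Cre on the KO side only. AhR battery genes, direct targets of the receptor, fell in 8 of 13 tested members (9 adjusted over the list alone), with a median of -1.59. Hic1 fell by 3.05 ± 0.46, the receptor's repressor Ahrr by 2.85 ± 0.47, Asb2 from 258 ± 40.5 to 35.7 ± 6.44 CPM (SD, n = 3) and Nqo1 by 1.93 ± 0.29. Cyp1a1, a classical target, stood at 0.465 ± 0.413 and 0.149 ± 0.109 CPM (adjusted p = 0.39). The list had adjusted p = 2.88e-10, and adjusted p = 0.296 with an estimated correlation. The other largest falls were in Adamtsl3 (-2.90 ± 0.40), Zmat4 (-2.84 ± 0.29) and the netrin receptor Unc5b (-2.78 ± 0.47). The largest rises were in Fibcd1 (2.44 ± 0.38), the tetraspanin Tspan32 (2.22 ± 0.37), the gap junction gene Gja1 (2.20 ± 0.34), Wnt7b (1.86 ± 0.38) and Tle6 (1.71 ± 0.30). Mamdc2 rose by 2.09 ± 0.42, a call lost without Ahr flox replicate 1 (0.0548) or 3 (0.0523).

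The stem cell factor receptor Kit fell by 1.86 ± 0.22, the inhibitory receptor Cd200r1 by 1.89 ± 0.35 and the chemokine receptor Cxcr3 by 1.26 ± 0.17, while Inpp4b rose by 0.93 ± 0.19. ILC1 and tissue residency genes had 5 of 15 lower and 1 higher (7 and 1 adjusted over the list alone; list adjusted p = 0.00104; adjusted p = 0.985 with an estimated correlation). The NK receptors Cd96 and Klrc3 fell by 1.29 ± 0.10 and 1.30 ± 0.19, with 5 of 25 receptors lower (7 lower and 2 higher adjusted over the list alone). The receptor list had adjusted p = 0.0992 (0.00792 without Ahr flox replicate 1 and 0.046 without Ahr KO replicate 2). The checkpoint genes Lag3 and Cd160 fell by 0.85 ± 0.13 and 2.20 ± 0.40, and Pdcd1, which encodes PD-1, rose by 2.82 ± 0.57 from 0.0368 ± 0.038 to 0.269 ± 0.0326 CPM. Cell cycle genes fell in 22 of 36 members (30 adjusted over the list alone) with a median of -0.38, such as Nusap1 (-0.57 ± 0.10) and Bub1b (-0.49 ± 0.09). Their list had adjusted p = 2.95e-18, and adjusted p = 0.605 with an estimated correlation. Circulating mature NK genes had 2 of 16 higher, Ly6c2 (1.46 ± 0.25) and the transcription factor Eomes (0.75 ± 0.16; adjusted p = 0.057 without Ahr flox replicate 1). Adjusted over the list alone 5 were higher (list adjusted p = 9.92e-04; adjusted p = 0.257 with an estimated correlation). Camera also called cholesterol synthesis (median 0.21; adjusted p = 9.92e-04), ribosome biogenesis (median 0.15; 0.0284) and mitochondrially encoded transcripts (median 0.26; 0.0116). Each was higher as a list (adjusted p = 0.985 with an estimated correlation), with 0 members called by edgeR, DESeq2 or limma voom and 1, 2 and 3 members at an unadjusted p under 0.05. Ribosome biogenesis lost its call without Ahr flox replicate 1 (0.612), Ahr KO replicate 2 (0.0645) or Ahr KO replicate 3 (0.178). The mitochondrially encoded list lost its call without Ahr flox replicate 1 (0.161) or Ahr KO replicate 2 (0.187). Nuclear-encoded oxidative phosphorylation genes had a median of -0.06 and 1 of 42 lower (0 adjusted over the list alone). Their list was not called (adjusted p = 0.0756), but was called lower without Ahr flox replicate 1 (4.86e-04), Ahr KO replicate 2 (0.0479) or Ahr KO replicate 3 (0.017).

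No list of other cell types was called in Ahr KO cells. T cell markers had 2 of 12 lower, Cd3g (-1.50 ± 0.30) and Cd3d (-1.06 ± 0.24; list adjusted p = 0.886). The Cd3d call was lost without Ahr flox replicate 1 (0.0614) or 3 (0.0692) or Ahr KO replicate 1 (0.0596), 2 (0.0655) or 3 (0.051). B cell markers had Ighm higher (0.53 ± 0.13) and Cd79b lower (-1.43 ± 0.38), with 1 higher and 2 lower adjusted over the list alone (list adjusted p = 0.704). The Ighm call was lost without Ahr flox replicate 1 (0.1) or Ahr KO replicate 1 (0.0653) or 3 (0.0863). That of Cd79b was lost without Ahr flox replicate 1 (0.0907) or 3 (0.16) or Ahr KO replicate 1 (0.0892) or 2 (0.147). Dendritic cell markers had H2-Eb1 higher (1.11 ± 0.28; 2 of 6 higher adjusted over the list alone). This call was lost without Ahr flox replicate 2 (0.0769) or 3 (0.101) or Ahr KO replicate 1 (0.0608), 2 (0.0508) or 3 (0.0766). The dendritic list had adjusted p = 0.112 and was called higher without Ahr flox replicate 3 (0.0436) or Ahr KO replicate 2 (0.0479). Macrophage and monocyte markers had Cd68 lower (-1.04 ± 0.20; list adjusted p = 0.886).

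HIF target and glycolysis lists were not called in Ahr KO cells (adjusted p = 0.982 and 0.874). Genes of the ATF4 and amino acid response had a median of 0.18 (list adjusted p = 0.154, but 0.0142 with same-numbered replicates as pairs and 0.0203 without Ahr flox replicate 2). Of the 28 HIF targets 3 were called lower, Rora (-2.22 ± 0.29), Car12 (-1.03 ± 0.15) and Anxa2 (-0.74 ± 0.13), all in the chromosome 9 run. The median over the list was 0.05 and the mean -0.09. In all 1159 genes were called, 359 higher and 800 lower (92 and 217 by at least 2-fold). With same-numbered replicates as pairs 2423 were called, 1034 higher and 1389 lower, and in a fit of the compared groups only 1697, 703 higher and 994 lower. The count fell to 467 without Ahr flox replicate 1, 557 without Ahr flox replicate 3, 761, 536 and 679 without Ahr KO replicates 1, 2 and 3.

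The Hif1a Ahr KO comparison asks what follows when both factors are deleted, with the same limit from Cre. All 19 glycolysis genes were lower, such as Pfkl (-2.66 ± 0.10), Aldoa (-1.97 ± 0.08), Pgam1 (-1.92 ± 0.08) and Pkm (-1.93 ± 0.08). So were 26 of 28 other HIF targets, such as P4ha1 (-2.67 ± 0.14) and Kdm3a (-1.40 ± 0.08). Medians were -1.93 and -1.64 (list adjusted p = 7.49e-28 and 1.97e-24), and both calls held with an estimated correlation (adjusted p = 0.0272 and 0.0156). The AhR battery was lower in 8 of 13 members, such as Selenbp1 (-3.38 ± 0.20), Asb2 (-2.79 ± 0.32) and Scin (-2.32 ± 0.31), and higher in Ugt1a6a (4.40 ± 0.47) and Nfe2l2 (0.63). Its list had adjusted p = 0.014, with 9 lower adjusted over the list alone (adjusted p = 0.82 with an estimated correlation). Among the largest rises were those of Ccn5 (6.60 ± 0.61, from 0.0182 ± 0.0315 CPM in flox cells), Ugt1a10 (4.61 ± 0.57), Ugt1a6a, Pdcd1 (4.28 ± 0.40) and Ugt1a9 (4.18 ± 0.46). The largest falls were in Smtnl2 (-4.60 ± 0.24), Mgarp (-4.30 ± 0.27), Ppp1r3g (-4.11 ± 0.36), Plcxd1 (-4.08 ± 0.18), the matrix metalloproteinase Mmp9 (-4.05 ± 0.90) and Thsd1 (-4.00 ± 0.28). In all 5245 genes were called, 2482 higher and 2763 lower, with 479 and 902 changed by at least 2-fold. A fit of the compared groups only called 3100, 1544 higher and 1556 lower.

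Genes of the ATF4 and amino acid response rose in 15 of 20 members (17 adjusted over the list alone), with a median of 0.83, such as the amino acid transporter Slc7a5 (1.58 ± 0.22) and Sesn2 (0.94 ± 0.10). That list had adjusted p = 1.3e-05 (adjusted p = 0.744 with an estimated correlation). Mitochondrially encoded transcripts rose in 12 of 13 members (13 adjusted over the list alone) with a median of 1.00, such as mt-Cytb (1.69 ± 0.22; list adjusted p = 1.73e-07; adjusted p = 0.355 with an estimated correlation). They made up 4.09 ± 0.45% of counts beside 2.03 ± 0.14% in Hif1a Ahr flox cells (SD, n = 3). Cholesterol synthesis genes fell in 14 of 23 members (17 adjusted over the list alone), such as Fdps (-1.01 ± 0.13; list adjusted p = 3.23e-05; adjusted p = 0.82 with an estimated correlation). ILC1 and tissue residency genes were lower in 9 of 15 members and higher in Inpp4b (2 higher adjusted over the list alone). Tmem176a stood at -2.43 ± 0.24, Itga1 at -1.87 ± 0.19 and Rgs1 at -1.74 ± 0.24 (list adjusted p = 0.00731; adjusted p = 0.82 with an estimated correlation). Cell cycle genes had 0 of 36 higher and 2 lower (1 adjusted over the list alone), with list adjusted p = 0.622 (0.028 without Hif1a Ahr flox replicate 2). Pcna fell by 0.31 ± 0.07. E2f1 stood at -0.26, a call lost without Hif1a Ahr flox replicate 1 (0.129) or 3 (0.142), or Hif1a Ahr KO replicate 1 (0.078), 2 (0.101) or 3 (0.0588). Lag3 fell by 1.23 ± 0.13, Jak3 by 1.31 ± 0.09, Pim2 by 1.23 ± 0.11 and the Fc receptor gene Fcgr3 by 0.91 ± 0.09, and Eomes rose by 0.77 ± 0.16. Neutrophil markers were lower in 5 of 5 members (list adjusted p = 0.00492; adjusted p = 0.596 with an estimated correlation), all under 2 CPM in Hif1a Ahr flox cells. The T cell gene Cd6 rose by 3.38 ± 0.78, with 2.37 ± 2.08 CPM (SD, n = 3) in Hif1a Ahr KO cells, while Cd3g (-3.29 ± 0.33) and Cd3d (-2.30 ± 0.25) fell (list adjusted p = 0.821). Among B cell markers Ighm rose by 0.97 ± 0.13 and Cd79b fell by 2.26 ± 0.40 (list adjusted p = 0.893). Dendritic cell markers and macrophage and monocyte markers had 2 members lower each, such as H2-Ab1 (-2.90 ± 0.16; list adjusted p = 0.476 and 0.578). Nuclear-encoded oxidative phosphorylation genes had 4 of 42 higher and 4 lower (2 and 2 adjusted over the list alone; list adjusted p = 0.678, but 0.0252 without Hif1a Ahr flox replicate 3). Checkpoint and costimulatory receptors had 2 of 14 higher, among them Pdcd1, and 7 lower. Their list had adjusted p = 0.0693 (0.0425 without Hif1a Ahr flox replicate 3 and 0.0389 without Hif1a Ahr KO replicate 3). It was 0.0319 with same-numbered replicates as pairs, though numbers failed the pairing rule in this line. NK receptors had 3 of 25 higher and 7 lower, such as Klri1 (-1.13 ± 0.12; list adjusted p = 0.384). Interferon response genes had 8 of 28 higher, such as Usp18 (1.41 ± 0.22), and 7 lower (8 and 8 adjusted over the list alone; list adjusted p = 0.893).

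**Figure D2:**
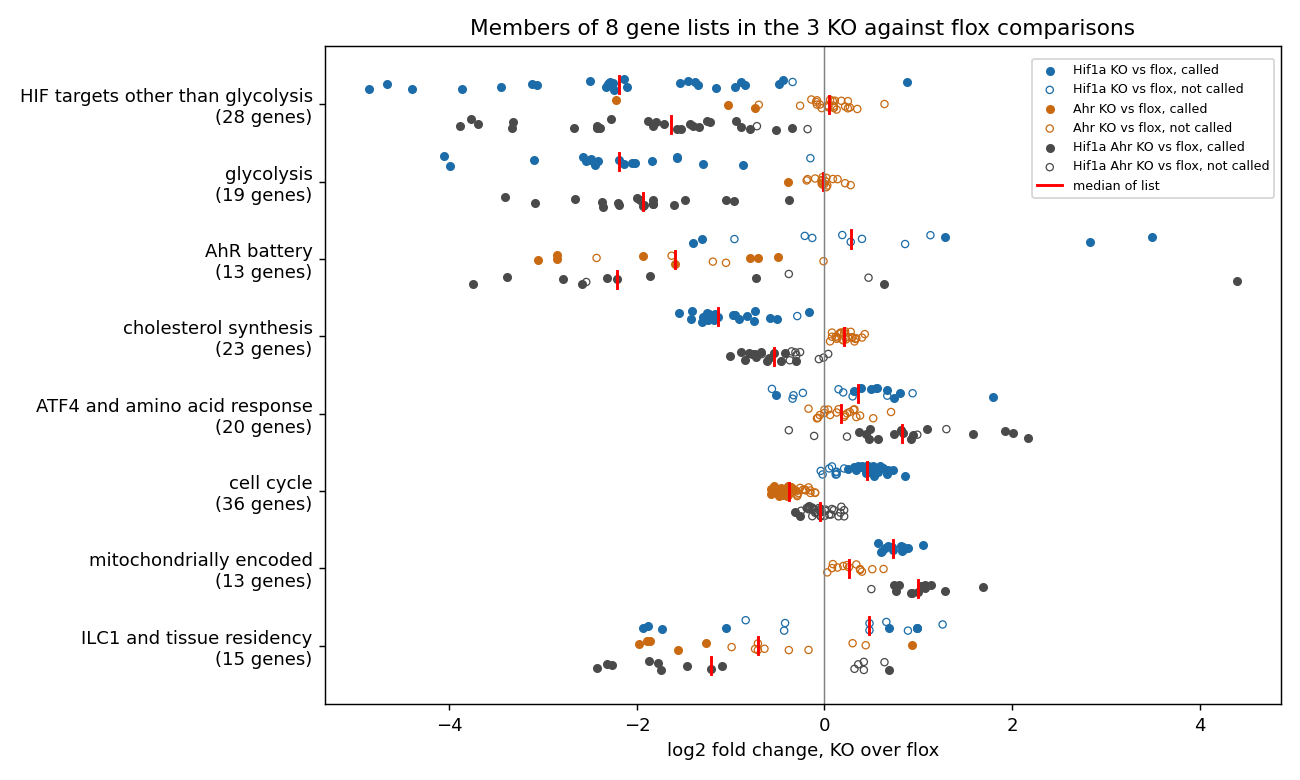
Log2 fold change of KO over flox (x axis) for every tested member of 8 gene lists (y axis) in the 3 main comparisons; filled points are called genes, open points were not called, and red bars are list medians. Glycolysis medians were -2.19, -0.02 and -1.93 in the Hif1a, Ahr and Hif1a Ahr lines, and AhR battery medians 0.28, -1.59 and -2.21.

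The 3 effects were compared with each other. Of 2984 genes called in both the Hif1a KO and the Hif1a Ahr KO comparison 95.8% went the same way. Shared calls included 1352 higher (436.9 expected if the calls were independent) and 1508 lower (490.8 expected). For Ahr KO and Hif1a Ahr KO, 82.9% of 604 shared calls went the same way, with 166 higher (53.2 expected) and 335 lower (132 expected). Hif1a KO and Ahr KO shared 774 calls, of which 18.3% went the same way, 42 higher (63.2 expected) and 100 lower (142.1 expected). Among calls of at least 2-fold, 12 higher (2.9 expected) and 30 lower (14.2 expected) were shared. Across genes, which are not independent replicates, their log2 changes correlated at -0.175 (Pearson) and -0.299 (Spearman).

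Directly tested, the Hif1a Ahr KO effect differed from the Hif1a KO effect in 1613 genes, 757 higher and 856 lower. The NK receptor Cd96 was lower by the double deletion relative to the single one (-1.24 ± 0.14), as were Prr5 (-1.38 ± 0.11), the serine racemase Srr (-1.36 ± 0.13) and Mvb12b (-0.95 ± 0.11). The semaphorin receptor Nrp1 (2.68 ± 0.28), Foxred2 (0.96 ± 0.11), B4galt5 (0.89 ± 0.10) and Sec61a2 (0.85 ± 0.10) were higher. The count was 801 without Hif1a Ahr flox replicate 1, 815 without Hif1a Ahr KO replicate 2, 857 and 873 without Hif1a flox replicates 1 and 3 and 754 without Hif1a KO replicate 2. It was 415 without the 2 libraries highest in T cell genes, Hif1a Ahr KO replicate 3 and Hif1a KO replicate 2, 978 in a fit of the compared groups only and 3159 with same-numbered replicates as pairs.

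Camera called 11 lists in this difference, 6 lower and 5 higher. No call held with an estimated correlation. Lower were the AhR battery (7 of 13 members, 9 adjusted over the list alone; list adjusted p = 3.65e-07; adjusted p = 0.442 with an estimated correlation) and cell cycle genes (18 of 36, 29 adjusted over the list alone; 4.51e-14; adjusted p = 0.475 with an estimated correlation). NK receptors were lower in 8 of 25 members (12 lower and 1 higher adjusted over the list alone; list adjusted p = 4.42e-05; adjusted p = 0.442 with an estimated correlation). Interferon response genes were lower in 6 of 28 (12 lower and 2 higher adjusted over the list alone; 3.43e-04; adjusted p = 0.622 with an estimated correlation). Autophagy genes were lower in 1 of 15 (0.0355; adjusted p = 0.442 with an estimated correlation). ILC1 and tissue residency genes had 4 of 15 lower and 1 higher (5 and 1 adjusted over the list alone; 0.00681; adjusted p = 0.783 with an estimated correlation). Higher were cholesterol synthesis (2 of 23, 10 adjusted over the list alone; 3.42e-07; adjusted p = 0.728 with an estimated correlation) and circulating mature NK genes (4 of 16, 6 adjusted over the list alone; 0.0326; adjusted p = 0.442 with an estimated correlation). Glycolysis was higher in 3 of 19 members (5 adjusted over the list alone; 0.00619) and ribosome biogenesis in 2 of 18 (3 adjusted over the list alone; 0.0311). The ATF4 and amino acid response was higher as a list (0.0257) with 0 of 20 members called by edgeR or limma voom, 3 by DESeq2 and 4 at an unadjusted p under 0.05. These 3 lists had adjusted p = 0.783 with an estimated correlation. Glycolysis lost its call without Hif1a Ahr KO replicate 1 (0.131). The ATF4 list lost it without Hif1a Ahr flox replicates 1 (0.0904) and 3 (0.0773), Hif1a Ahr KO replicates 1 (0.0657) and 2 (0.173), Hif1a flox replicate 3 (0.136) and Hif1a KO replicate 2 (0.099). Ribosome biogenesis lost it without Hif1a Ahr flox replicates 1 (0.207) and 2 (0.106), Hif1a Ahr KO replicate 1 (0.169), Hif1a flox replicate 2 (0.0847) and Hif1a KO replicate 2 (0.0653). Circulating mature NK genes lost it without Hif1a Ahr flox replicate 3 (0.0668), Hif1a Ahr KO replicate 3 (0.11) and Hif1a KO replicate 1 (0.0615). Autophagy lost it without Hif1a Ahr flox replicates 2 (0.0866) and 3 (0.0511), Hif1a Ahr KO replicate 3 (0.0653), Hif1a flox replicate 2 (0.0847) and Hif1a KO replicate 1 (0.0615).

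Relative to the Ahr KO effect, the Hif1a Ahr KO effect differed in 2749 genes, 1439 higher and 1310 lower. The secreted peptide gene Apln (-4.48 ± 0.18), Plcxd1 (-3.91 ± 0.23), Pfkl (-2.67 ± 0.14) and Aldoa (-1.95 ± 0.11) were lower, and Ugt1a7c (3.59 ± 0.26), Ttc39c (3.35 ± 0.24), Ppic (2.22 ± 0.19) and Arid5a (1.11 ± 0.09) higher. The Hif1a KO effect and the Ahr KO effect differed in 5415 genes, 2781 higher and 2634 lower. The effect on Apln differed by -4.84 ± 0.18, on Pfkl by -3.12 ± 0.14, on Slc2a1 by -2.66 ± 0.13 and on Aldoa by -2.39 ± 0.11. Apln stood at 1.02 ± 0.0788 CPM in Hif1a KO and 44.1 ± 6.75 CPM in Ahr KO cells, levels that come from different lines. Ttc39c (3.92 ± 0.24), the adaptor gene Sla (3.89 ± 0.22), Cd96 (1.87 ± 0.14) and St3gal6 (1.28 ± 0.10) were higher in that test. Cell cycle genes were higher in it in 32 of 36 members and lower in 0, with a median of 0.81 (list adjusted p = 7.05e-15; adjusted p = 0.557 with an estimated correlation).

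A departure of the Hif1a Ahr KO effect from the sum of the single effects was called in 6 genes, all higher: Bnip2 (0.86 ± 0.09), Ppib (0.97 ± 0.11), Usp3 (0.88 ± 0.10), Rab8b (0.90 ± 0.13), Snx1 (0.84) and Tpm1 (0.76). At an unadjusted p under 0.05 there were 998 of 16747 genes, where chance alone would leave a share of about 0.05. DESeq2 called 24, of which 20 were higher and 12 lay outside the run described next. With same-numbered replicates as pairs 35 were called, 30 higher and 5 lower, of which 26 lay outside it. The 6 genes lie in 1 run of neighbouring genes on chromosome 9, from Ppib to Bnip2 in the annotation's order. Of the 18 genes of this run with at least 2 CPM, 15 were called lower in all 3 KO groups. Medians were -0.92, -0.98 and -1.12 in the Hif1a, Ahr and Hif1a Ahr lines. The neighbour before the run, Csnk1g1, stood at 0.55, 0.45 and 0.62, and the one after it, Gtf2a2, at 0.46, 0.00 and 0.49. Among 10680 windows of 15 neighbouring genes across the genome, scored by the comparison closest to 0, the lowest in the run was -0.92 and the lowest elsewhere -0.18. The called count was 10 without Hif1a Ahr flox replicate 2 or 3 (9 higher and 1 lower each). It was 14 without Hif1a Ahr KO replicate 1, with 6 higher and 8 lower, and 9 of these lay outside the run. Across the genome 98 genes were lower and 42 higher in all 3 comparisons, of which 16 and 4 lie in the run or next to Ncr1. For the other 82 and 38 an effect of Cre cannot be told apart from effects of the deletions.

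**Figure D3:**
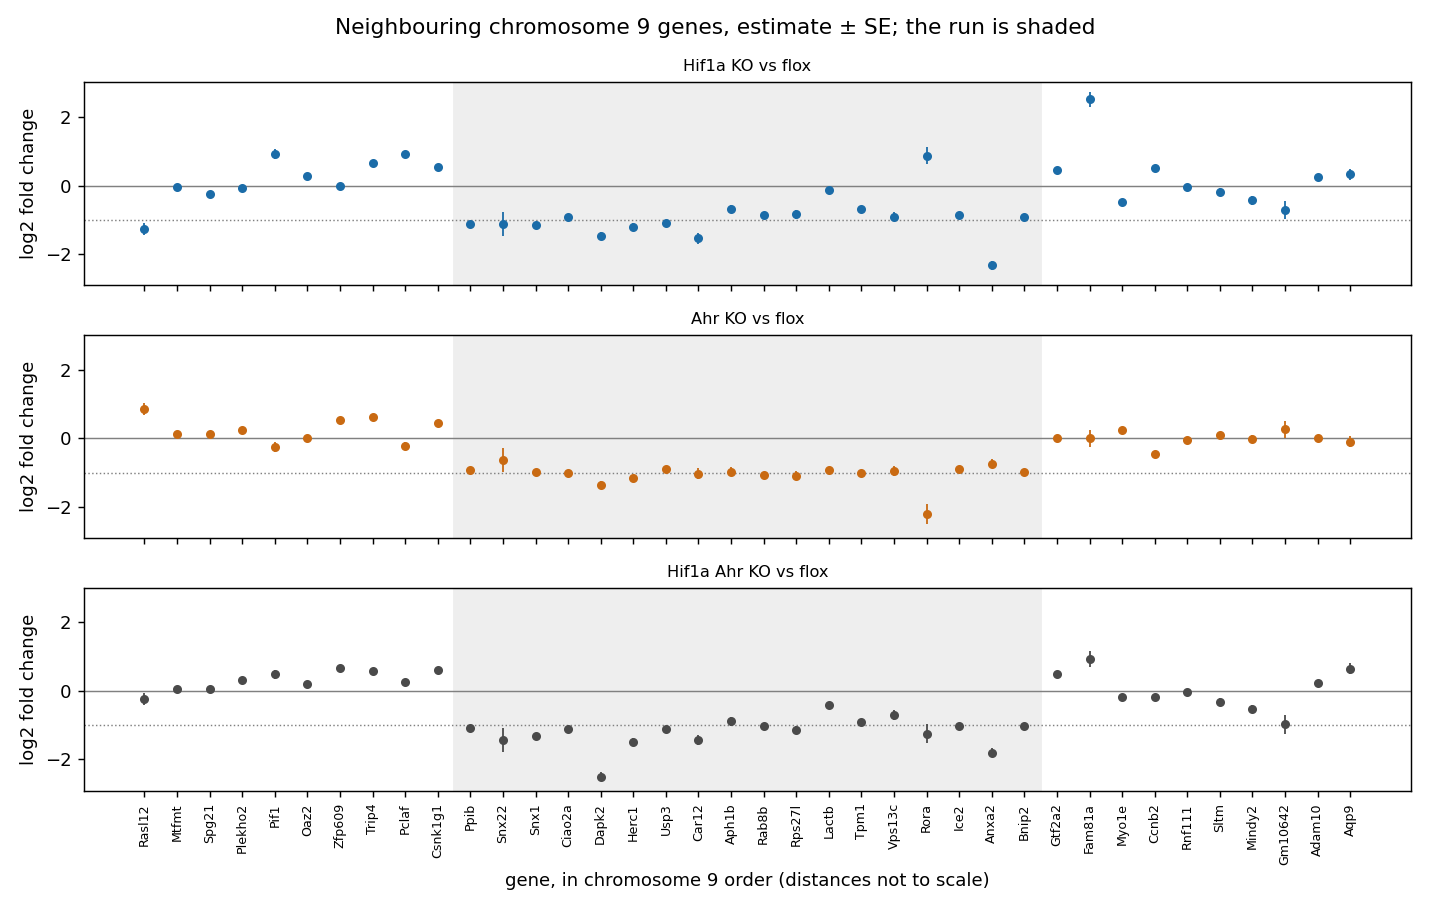
Log2 fold change with SE (y axis) of neighbouring genes in chromosome 9 order (x axis, distances not to scale) in the 3 main comparisons; the run from Ppib to Bnip2 is shaded and the dotted line marks a log2 change of -1. The median over the run was -0.92, -0.98 and -1.12, with Rora (0.88), Anxa2 (-2.33) and Lactb (-0.13) furthest from it in Hif1a KO cells.

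The 3 flox groups, which per the labels carry no Cre, were compared with each other. An F test called 41 genes between them, 27 without Ahr flox replicate 1, and DESeq2 called 108. At an unadjusted p under 0.05 there were 1111 of 16747 genes, where chance alone would leave a share of about 0.05. Nbea stood at 16.8 ± 2.07 CPM (SD, n = 3) in Hif1a flox cells beside 1.65 ± 0.171 in Ahr flox and 1.25 ± 0.265 in Hif1a Ahr flox cells. The complex I gene mt-Nd3 stood at 22.6 ± 5.17 CPM in Ahr flox cells beside 116 ± 24.2 and 145 ± 25. Snapc1, a neighbour of Hif1a on chromosome 12, stood at 33.3 ± 0.932 CPM in Ahr flox cells beside 13.98 ± 1.33 and 14.9 ± 0.905. The other named genes were Klhdc2, on chromosome 12, and Dynlt1b, Tulp4, Rnaset2b and Rsph3b, on chromosome 17. Their largest differences between 2 groups were 0.78, 2.56, 1.48, 1.12 and 1.14 (log2). Dynlt1b and Rnaset2b have close paralogs. Chromosomes 12 and 17 held 10 and 12 of the 41 called genes, 53.7% together, beside 8.5% of the genes tested.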

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

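The tests of explanations for the chromosome 9 run, the mitochondrially encoded transcripts and the flox groups, the splits of the 3 main comparisons, and the sorting of the other splits by the libraries they mix or part, were chosen only after the result was seen; the splits of the other tests were planned before their values were seen.

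The effect of the double deletion differed from that of the single Hif1a deletion, by a test of the difference itself, in 1613 genes. By log2 difference Nrp1 (2.68), Foxred2 (0.96), B4galt5 (0.89) and Sec61a2 (0.85) were higher, and Prr5 (-1.38), Srr (-1.36), Cd96 (-1.24) and Mvb12b (-0.95) lower. The count was 801 without Hif1a Ahr flox replicate 1, 815 without Hif1a Ahr KO replicate 2, 857 without Hif1a flox replicate 1, 873 without Hif1a flox replicate 3 and 754 without Hif1a KO replicate 2. Without the 2 libraries highest in T cell genes, Hif1a Ahr KO replicate 3 and Hif1a KO replicate 2, it was 415, in a fit of the compared groups only 978, and with same-numbered replicates as pairs 3159. Of 100 splits of the 12 libraries 1 called as many genes, the real one, and the highest other called 1451. For the count from all libraries the share lies under 0.05, which speaks against a chance sorting of KO and flox libraries jointly. It cannot decide on the sorting of the KO libraries alone, because the splits re-sorted the flox libraries too, and decides nothing further. The lower counts lie under 1451 and had no splits of their own. The 92 splits that mixed the Ahr-deleted KO libraries between the groups called at most 15. The other 7, which kept them together and so carry the effect under test, called 270 to 1451. For the lists 14 of 100 splits called at least the real 11, the highest 15. No split of 3 and 3 balances the libraries with a deletion, so every count of genes or lists carries part of its effect. Chance stays open for the lists, here and in the next 2 tests.

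Relative to the single Ahr deletion, 2749 genes differed. Ugt1a7c (3.59), Ttc39c (3.35), Ppic (2.22) and Arid5a (1.11) were higher, and Apln (-4.48), Plcxd1 (-3.91), Pfkl (-2.67) and Aldoa (-1.95) lower. For called genes 6 of 100 splits reached the real count, with 4838 as the highest other. The 5 others kept the Hif1a-deleted KO libraries together and so carry the effect under test, while the 91 splits that mixed them called at most 1 gene, so the share does not decide on chance. Splits that only swap the lines were not removed. A split with the Hif1a-deleted KO libraries on the subtracted side matched the real counts, with 2749 genes and 8 lists. For the 8 called lists 58 of 100 splits reached the real count, with 15 as the highest other; the calls for glycolysis and the other HIF targets held with an estimated correlation (adjusted p = 0.0135 and 0.0126). The effects of the single deletions differed from each other in 5415 genes. Ttc39c (3.92), Sla (3.89), Cd96 (1.87) and St3gal6 (1.28) were higher after Hif1a deletion relative to Ahr deletion, and Apln (-4.84), Pfkl (-3.12), Slc2a1 (-2.66) and Aldoa (-2.39) lower. Here 3 of 100 splits called as many genes, the real one included, with 6132 as the highest other. The share lies under 0.05, which speaks against a chance sorting of KO and flox libraries jointly. It cannot decide on the sorting of the KO libraries alone, because here too the splits re-sorted the flox libraries, and decides nothing further. The 15 other splits that kept the Hif1a-deleted KO libraries together carry the effect under test and called 4383 to 6132. The 84 splits that mixed the Hif1a-deleted KO libraries with the others called 0 genes each by edgeR. The 12 called lists were reached by 9 of 100 splits, the highest other at 13. With an estimated correlation camera called only 1 list in this test.

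The test of departure from additivity called 6 genes, with log2 differences of 0.97 (Ppib), 0.90 (Rab8b), 0.88 (Usp3) and 0.86 (Bnip2) for the named ones. The count was 10 without Hif1a Ahr flox replicate 2 or 3 and 14 without Hif1a Ahr KO replicate 1, of which 8 were lower. Camera called 8 lists, and none with an estimated correlation or by fry. Of 100 splits 64 called at least 6 genes, the highest other 6031, and 68 called at least the real 8 lists, the highest other 14. These splits decide nothing on chance. All but 1 of the others leave the effect of a deletion in the contrast, and the 3 that put all Hif1a-deleted or all Ahr-deleted KO libraries on the subtracted side called 1475 to 6031 genes, which points to the deletions as the structure of the samples. The 1 that balances both called 2 genes and 2 lists. Like the real grouping, it leaves a net weight of -3 on the KO libraries. What all KO libraries share, such as the lower chromosome 9 run, therefore stays in its contrast.

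The chromosome 9 run was weighed first. Separate effects of Hif1a and Ahr that add up would leave it near 0 in the test of departure from additivity. Its median there was 0.83 (lower quartile 0.75), so on these genes the double effect fell short of the sum of the single ones. The run was picked after these same effects were seen, so neither this value nor the medians of the run are an independent test. A candidate explanation is that the chromosome that carries Cre has 1 missing copy of the run, since the median closest to 0 among the 3 comparisons was -0.92, near the -1 that 1 of 2 copies gives. Whether the run accounts for the departure from additivity stays open: all 6 genes called by the main fit lay in it, but 9 of 35 with same-numbered replicates as pairs and 5 of 14 without Hif1a Ahr KO replicate 1. Where Cre was inserted is not stated and gene-level counts hold no test of it; Ncr1 and its chromosome 7 neighbours Lilra5, Gm15931 and Gp6 rose in all 3 lines, and Gm44881 in 2, with 2.75 (adjusted p = 0.0747) in the Ahr line. Of its 18 genes with at least 2 CPM, Rora (0.88), Anxa2 (-2.33) and Lactb (-0.13) lay furthest from the run's median in Hif1a KO cells.

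The rise of mitochondrially encoded transcripts after Hif1a deletion was weighed next. Scaling between libraries is argued against, because 1 factor per library would move nuclear-encoded subunits as far, and their upper quartile was 0.18 beside a lower quartile of 0.65 for the mitochondrially encoded genes. An effect of Cre alone would cancel between lines, but the Hif1a KO effect minus the Ahr KO effect had a median of 0.49 (lower quartile 0.41). This argues against Cre as the whole cause only. In Ahr KO cells, which carry Cre, the mitochondrially encoded list had a median of 0.26 (quartiles 0.14 and 0.38), so a part from Cre stays open. More mitochondria per cell with nuclear-encoded subunits raised alike is argued against by the same quartiles and the median of 0.11 of these subunits. An effect of Hif1a loss itself may account for the rise and stays open as a hypothesis; stress of the cells in culture was not tested.

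Differences between the flox groups were weighed last. Of 41 called genes 22 lay on chromosomes 12 and 17 (53.7% beside 8.5% of tested genes), and the count was 27 without Ahr flox replicate 1. Both Hif1a and Ahr lie on chromosome 12, so segments of other strain origin around the targeted alleles are a candidate explanation for that chromosome; no sequence was analysed here, and the segment on chromosome 17 has no targeted gene. Of 100 splits of the 9 flox libraries 2 called as many genes, the real one included, with 41 as the highest other. A share under 0.05 makes chance unlikely for the count but does not exclude it, since 1 other split also called 41 genes. The count of 27 had no splits of its own. Same-numbered Hif1a Ahr and Ahr flox libraries deviated together; the 46 other splits that part all 3 such pairs, as the real one does, called at most 29.

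In the main comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05. Hif1a KO called 5923 genes beside at most 1 in another split (1 of 10 as large) and 12 lists beside at most 11 (1 of 10). Ahr KO called 1159 genes beside 0 by edgeR in the other splits (1 of 10) and 7 lists beside at most 10 (4 of 10). Hif1a Ahr KO called 5245 genes beside at most 4 (1 of 10) and 8 lists beside at most 14 (8 of 10). The list counts of Ahr KO and Hif1a Ahr KO thus lay within the range of the other splits, and chance stays open for them. With at most 4 genes called, the other splits still called 5 to 11, 3 to 10 and 5 to 14 lists in the Hif1a, Ahr and Hif1a Ahr lines. Camera at its preset correlation can therefore call lists without the real grouping, though these splits carry part of the effect of a deletion. In the Hif1a and Ahr lines, where same-numbered libraries deviated together, splits that part all 3 pairs called 0 genes each and at most 8 and 6 lists, while the other splits keep 1 pair or more on the same side.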

How the results depend on the processing

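The sex ratio covariate, leaving out genes linked to the Cre locus and leaving out the 2 libraries highest in T cell genes were chosen only after the data were seen; the other alternatives were planned. Of 5668 alternative values for 325 results of named genes 5354 kept direction and side of the threshold, 306 were weaker, 8 stronger and none reversed; 132 of the weaker came from the rule on fold change and 120 from leaving out 1 library. Unless shown by an alternative's own construction, the cause was not tested.

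With the replicate block (paired libraries) Ahr KO called 2423 genes and Hif1a KO 6814. The block changed no other called count of these 2 comparisons by over 1.5 times; it changed the calls of the TCA cycle and ATF4 lists and of Ahr. In the Hif1a Ahr line numbers did not pair libraries; with the block the double minus single Hif1a effect gave 3159 genes and additivity 35 (30 higher, 5 lower; 9 in the chromosome 9 run), and the Hif1a Ahr KO comparison 6256, with Ahr called lower (-0.27; adjusted p = 0.0162) and the checkpoint list called (0.0319).

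By construction, an absolute log2 fold change of at least 1 left 1615 genes for Hif1a KO, 309 for Ahr KO and 1381 for Hif1a Ahr KO. It left 482 and 972 for the double effect minus the Hif1a and Ahr effects, 2173 for the Hif1a minus the Ahr effect and 0 for additivity (998 at an unadjusted p under 0.05, edgeR). Shared calls under it were 225 higher and 551 lower (Hif1a KO and Hif1a Ahr KO), 34 and 106 (Ahr KO and Hif1a Ahr KO) and 12 and 30 (Hif1a KO and Ahr KO; 2.9 and 14.2 expected). Fitting only the groups compared, with fewer libraries, gave 3100 for Hif1a Ahr KO and 978 for the double minus Hif1a effect. DESeq2 gave 24 for additivity, 108 between flox groups, and 255 and 66 shared higher calls of Ahr KO with Hif1a Ahr KO and Hif1a KO. Additivity fell to 0 without genes linked to the Cre locus, which held all 6 by edgeR, and the double minus Hif1a effect to 415 without the 2 libraries.

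Lists called by camera with an estimated correlation were 2, 0 and 2 for Hif1a, Ahr and Hif1a Ahr KO, 0, 2 and 1 for the 3 differences of effects and 0 for additivity. With fry they were 20, 3 and 15, 7 for the double minus Hif1a effect and 0 for additivity.

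Leaving out 1 library gave 4787 to 5445 called genes for Hif1a KO, 467 to 1333 for Ahr KO (557, 536, 679 and 761 in between) and 3792 to 5528 for Hif1a Ahr KO. The double minus Hif1a effect gave 754 to 2405, the double minus Ahr effect 2045 to 3139, the Hif1a minus Ahr effect 4615 to 5252, additivity 5 to 14 (at 14, without Hif1a Ahr KO replicate 1, 6 higher and 8 lower) and flox groups 27 to 45. Called lists ranged 8 to 13, 7 to 8 and 8 to 11 in the main comparisons, 8 to 14, 7 to 10 and 9 to 13 for differences and 4 to 10 for additivity. With 3 libraries a group, simulated 1.5-fold changes were recovered in 38.8% to 56.7% of genes, so small effects are missed at this depth and spread.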

Other observations

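The genes in this part, and the sums of T cell and sex-linked genes, were chosen only after their values were seen; the tests of differences between effects were planned. Several genes moved in opposite directions after the single deletions. The secreted peptide gene Apln fell by 4.23 ± 0.14 (log2, SE) in Hif1a KO cells and rose by 0.60 ± 0.11 in Ahr KO cells, and fell by 3.88 ± 0.14 with both deletions. Nqo1 stood at 0.797 ± 0.271 CPM in Hif1a flox and 5.7 ± 0.414 in Hif1a KO cells (SD, n = 3), but at 0.890 ± 0.148 in Ahr flox and 0.232 ± 0.0378 in Ahr KO cells; the difference of effects was 4.76 ± 0.38 (adjusted p = 7.39e-08). The adaptor gene Sla rose by 2.15 ± 0.15 in Hif1a KO cells, fell by 1.73 ± 0.16 in Ahr KO cells and rose by 0.67 ± 0.15 with both deletions. Spp1, which encodes osteopontin, fell from 7293 ± 1220 to 1326 ± 473 CPM in Hif1a KO cells and stood at 7294 ± 1040 and 15010 ± 780 CPM in Ahr flox and Ahr KO cells. Its Hif1a KO effect minus its Ahr KO effect was -3.50 ± 0.38 (adjusted p = 9.3e-06).

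For other genes the level with both deletions stands beside those of the single deletions. These groups come from different mouse lines, so levels alone do not tell an effect of a deletion from a difference between lines. A difference of effects is given here for Kit only. Kit stood at 429 ± 55.9 CPM in Hif1a KO, 76.2 ± 15.4 in Ahr KO and 127 ± 26.8 in Hif1a Ahr KO cells (SD, n = 3), with a double effect below the Hif1a effect (-2.21 ± 0.30; adjusted p = 0.00121). Eomes stood at 213 ± 41.4, 450 ± 36.9 and 461 ± 40.9 CPM in the same groups. The class II gene H2-Ab1 stood at 5.14 ± 0.87 CPM in Hif1a KO, 49.0 ± 2.8 in Ahr KO and 5.30 ± 1.55 in Hif1a Ahr KO cells.

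Next to Ncr1 on chromosome 7, Lilra5 was higher in all 3 KO groups (log2 changes of 7.06, 6.07 and 6.72 in the Hif1a, Ahr and Hif1a Ahr lines). So were Gm15931 (9.32, 5.30 and 9.51) and Gp6 (1.14, 2.11 and 1.21), all at low levels, while Gm44881 (5.44, 2.75 and 5.67) was not called in the Ahr line (adjusted p = 0.0747); Lilra5 was at 0 in all Hif1a Ahr flox libraries and at 0.237 ± 0.101 CPM in Hif1a Ahr KO cells. The T cell genes Cd3e, Cd6, Cd8a and Cd8b1 summed to 23.6 CPM in Hif1a Ahr KO replicate 3 and 9.82 CPM in Hif1a KO replicate 2, beside at most 7.79 CPM in the other libraries. Xist, expressed from the inactive X chromosome of females, and Y-linked genes were both present in every library, Xist at 88.1 to 433 CPM and Y-linked genes at 50.4 to 176 CPM.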
